A study of Rattus norvegicus with 16 samples.

How the data were processed

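RNA from 10 mg of right ventricle of female Sprague Dawley rats, 20 to 21 weeks old, was sequenced as stranded mRNA libraries (TruSeq Stranded mRNA). The rats were wild type (WT) or carried a mutation of estrogen receptor alpha (ERalpha −/−, called KO here), and had sham surgery (SHAM) or 10 weeks of pulmonary artery banding (PAB), which narrows the pulmonary artery and loads the right ventricle with pressure. Each of the 4 groups holds 4 libraries, 16 in all, named here by group and replicate number. The labels do not say that the replicates of a group are separate animals, so the p-values measure the spread between these samples.

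The deposited values are expected counts, one whole number per gene symbol and library. The authors name STAR 2.5.3a, RSEM 1.3.0 and the rat build Rnor_6.0. They do not state the annotation, the strand setting of the counting, or how the RSEM estimates became whole numbers. The values were checked to be whole numbers of at least 0 with totals that differ between libraries. Each file lists 32754 gene entries, of which 13748 were 0 in every library, and 274 symbols occur more than once. Entries with a repeated symbol were kept apart and not summed. The gene table used to match symbols and to find neighbours of Esr1 is for another rat assembly (GRCr8), so no coordinates are given.

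Genes were tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, genes with too few counts were removed by filterByExpr with its defaults (min.count 10), and a quasi-likelihood model with robust dispersion was fitted to the 4 group means over all 16 libraries. This left 13458 genes, which hold at least 99.9% of the counts of each library. Comparisons were banding within each genotype, genotype within each surgery, the interaction (the banding effect in KO minus that in WT), and the mean of each pair of within-group effects. A gene was called past the test at a Benjamini-Hochberg adjusted p below 0.05 within a comparison, with no minimum fold. The standard error (SE) of a log2 fold change was taken as its size over the square root of the F statistic. Levels are CPM (counts scaled to the TMM-adjusted library total by the cpm function of edgeR), given as mean ± SD with n = 4.

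Before the data were examined, 41 gene lists were fixed for pathways of the loaded heart and for markers of the cell types a piece of right ventricle could hold. The 40 lists with at least 5 tested members were tested with camera at its preset correlation of 0.01 and adjusted over lists within a comparison. Camera with an estimated correlation, and fry, which asks whether a list's genes move on balance 1 way, were run beside it. With the estimated correlation no list passed in any of the 7 comparisons. A score per library is the mean z-score of log2(CPM + 1) over a list's tested genes. Scores were compared by two-sided exact permutation tests, which with 4 against 4 cannot go below 0.0286. Adjusted over 40 lists, such a test can pass only if many lists reach that floor together, so its failure decides little.

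The genes named in each comparison follow a rule also fixed in advance. It takes up to 12 rises and 12 falls with the largest log2 fold change among genes past the test, with a mean of at least 1 CPM, no overlap between the groups in each genotype or surgery, and a symbol that is not a placeholder. It adds up to 4 members with the smallest p from each list that passed or held a changed gene, and a fixed set of receptor, natriuretic peptide, myosin, actin, collagen and signalling genes that is given throughout. Which of those lists the text describes was chosen after their values were seen, and counts over every list are given beside them. Results for some single genes are not reported here.

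Alternatives chosen in advance were RLE size factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter on low counts, a stricter filter (at least 1 CPM in 4 libraries), replicate number as a block, a fit to only the groups compared, a minimum fold of 1.5, camera with an estimated correlation, and leaving out each library in turn. Added after the data were seen were a fit without 3 sham libraries whose adipocyte and mesothelial scores both exceed 0.4, a fit with the sum of those scores as a covariate, and limma-voom with library quality weights. The replicate numbers did not pair the samples, since 2 of 16 libraries correlated best with a library of their own number.

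The procedure was tested on simulated data with the design and depth of this study. In each comparison within a genotype or surgery it recovered 22.4% to 32.8% of genes changed 1.5-fold, 56.7% to 65.7% of those changed 2-fold and 86.4% to 89.4% of those changed 4-fold. For the banding effect averaged over genotypes the shares were 55.2%, 73.1% and 95.5%, and for the interaction 13.4%, 50.7% and 69.7%. The simulated data drew each gene on its own, without the difference shared by the sham libraries high in adipocyte and mesothelial scores. In comparisons that use a sham group, recovery in the real libraries may therefore be lower than these shares. Totals of 22168110 to 34718633 counts per library set the counting error. Averaged over genes, every pair of replicates differed by more than counting error alone gives. This was not split by level of expression.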

Results

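The right ventricle of female rats was profiled by RNA sequencing in a design that crosses genotype with surgery. WT and ERalpha −/− (KO) rats had sham surgery or pulmonary artery banding for 10 weeks, with 4 libraries in each of the groups WT SHAM, WT PAB, KO SHAM and KO PAB. Total counts per library were 22168110 to 27598074 in WT SHAM, 27733987 to 32411398 in WT PAB, 23270079 to 34718633 in KO SHAM and 25778652 to 29210819 in KO PAB. Mitochondrially encoded transcripts took 33.6% to 42.8% of the counts of a library, with group means of 36.9% to 38.0%. The comparisons ask how the right ventricle responds to pressure load, what loss of ERalpha changes with and without load, and whether the response to load depends on ERalpha.

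Esr1, which encodes ERalpha, was low in every KO library. It had 91 to 139 counts in WT SHAM, 70 to 131 in WT PAB, 10 to 21 in KO SHAM and 7 to 13 in KO PAB. Its level was 4.31 ± 0.824 CPM in WT SHAM, 3.80 ± 1.00 in WT PAB, 0.541 ± 0.0780 in KO SHAM and 0.371 ± 0.102 in KO PAB (SD, n = 4). Every library therefore had the Esr1 level of its labelled genotype. The gene for the other nuclear estrogen receptor, Esr2, had at most 1 count in any library. The progesterone receptor gene Pgr had 109 counts in WT SHAM 2, 18 in WT SHAM 3, 32 in KO SHAM 4 and at most 3 in any other library. Both were too low to be tested. The membrane estrogen receptor gene Gper1 did not pass the test in any comparison.

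**Figure D1:**
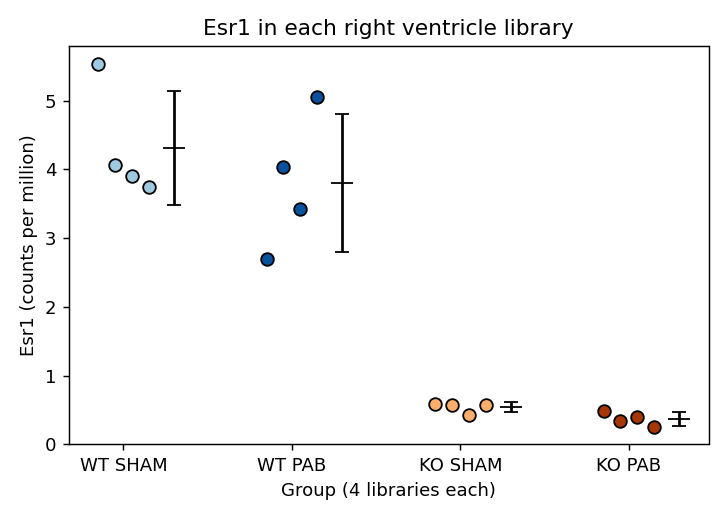
Esr1 level in CPM for each library, by group, with the group mean and SD (n = 4) as a bar beside the points. All 8 KO libraries lie below all 8 WT libraries.

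3 sham libraries stood apart from the other 13. WT SHAM 2, WT SHAM 3 and KO SHAM 4 had the highest values on the first principal component, which held 34.7% of the variance, while on the second, with 15.5%, all 8 sham libraries had negative values and 7 of 8 banded libraries positive ones (WT PAB 4 was the exception). Against the other 5 sham libraries their median log2 difference was 4.37 over the adipocyte markers, 3.14 over the mesothelial markers, 1.73 over fibrillar matrix genes and 1.39 over smooth muscle and pericyte markers. Adipoq, which encodes the adipocyte hormone adiponectin, averaged 28.3 CPM in the 3 and 0.0254 CPM in the 5. Msln, a mesothelial surface protein, averaged 35.6 and 3.70 CPM, and Myh11, the smooth muscle myosin heavy chain, 608 and 72.1 CPM. Cartilage and valve (2.85 over 6 genes), lymphatic endothelial (1.40), macrophage and monocyte (1.19) and fibroblast markers (1.15) and genes of cytokines and complement (1.02) were also higher in the 3. Sarcomere genes were lower in the 3, with a median difference of −0.47, and nuclear genes of oxidative phosphorylation differed by −0.53. The 3 libraries fall in the sham groups, so comparisons that use a sham group also carry this difference.

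**Figure D2:**
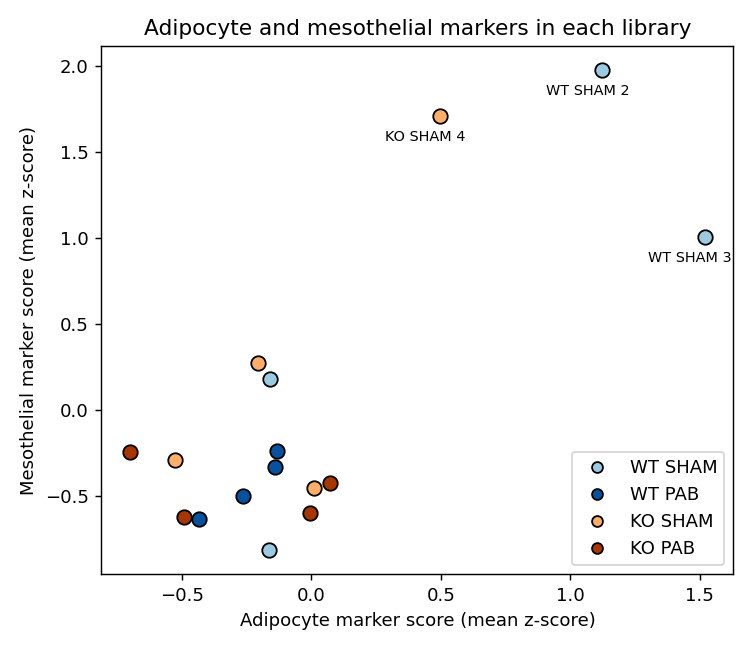
Adipocyte marker score against mesothelial marker score (mean z-scores, no unit) for each of the 16 libraries, coloured by group. WT SHAM 2, WT SHAM 3 and KO SHAM 4 exceed 0.4 on both scores and the other 13 libraries do not.

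Banding was first averaged over both genotypes, to ask what pressure load does to the right ventricle in either. Genes of the stretched and stressed cardiomyocyte rose. Nppa, which encodes atrial natriuretic peptide, rose by a log2 fold change of 5.46 (SE 0.66, adjusted p 0.00176), from 10.3 ± 5.77 to 157 ± 204 CPM in WT and from 5.65 ± 2.81 to 718 ± 350 CPM in KO (SD, n = 4). Skeletal alpha-actin (Acta1) rose by 2.70 (SE 0.33, adjusted p 0.00176), the titin-associated stretch protein gene Ankrd23 by 3.51 (SE 0.50, adjusted p 0.00335) and the slow myosin heavy chain Myh7 by 1.68 (SE 0.29, adjusted p 0.00599). B-type natriuretic peptide (Nppb) rose by 2.13 (SE 0.52, adjusted p 0.0312), and the adult fast myosin Myh6 differed by −0.17 without passing the test (adjusted p 0.591).

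685 of 13458 genes passed the test in this comparison, 436 higher and 249 lower after banding, of which 280 differed by over 1.5-fold. Among genes whose groups did not overlap in either genotype, other large rises were in Cdhr1 (3.22), Tceal7 (3.21), Sypl2 (3.03), Rbm44 (2.98), Akip1 (2.63), Efcab6 (2.25), the phosphatase gene Dusp15 (2.21), the vasohibin gene Vash2 (2.09) and the Z-disc protein gene Myot (1.97). The largest falls among such genes, which leaves out larger falls given below, were in the unconventional myosin Myo16 (−1.83), the membrane skeleton gene Epb41l3 (−1.54) and the transcription cofactor Lmo3 (−1.26). Further falls were in Lsamp (−0.97), Gpm6a (−0.95), Abca8 (−0.94), Alcam (−0.87), Cdh19 (−0.84), the sodium channel gene Scn7a (−0.80), Plekhb1 (−0.79), Gca (−0.79) and the organic cation transporter Slc22a3 (−0.71). The SE of these 21 genes were 0.13 to 0.47, and each gene separated the groups without overlap in both genotypes. Abca8, Cdh19 and Gca missed the threshold in 6, 9 and 1 of 26 alternative fits, with adjusted p of 0.00194 to 0.104, 0.00466 to 0.0809 and 0.000600 to 0.0536 over them.

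**Figure D3:**
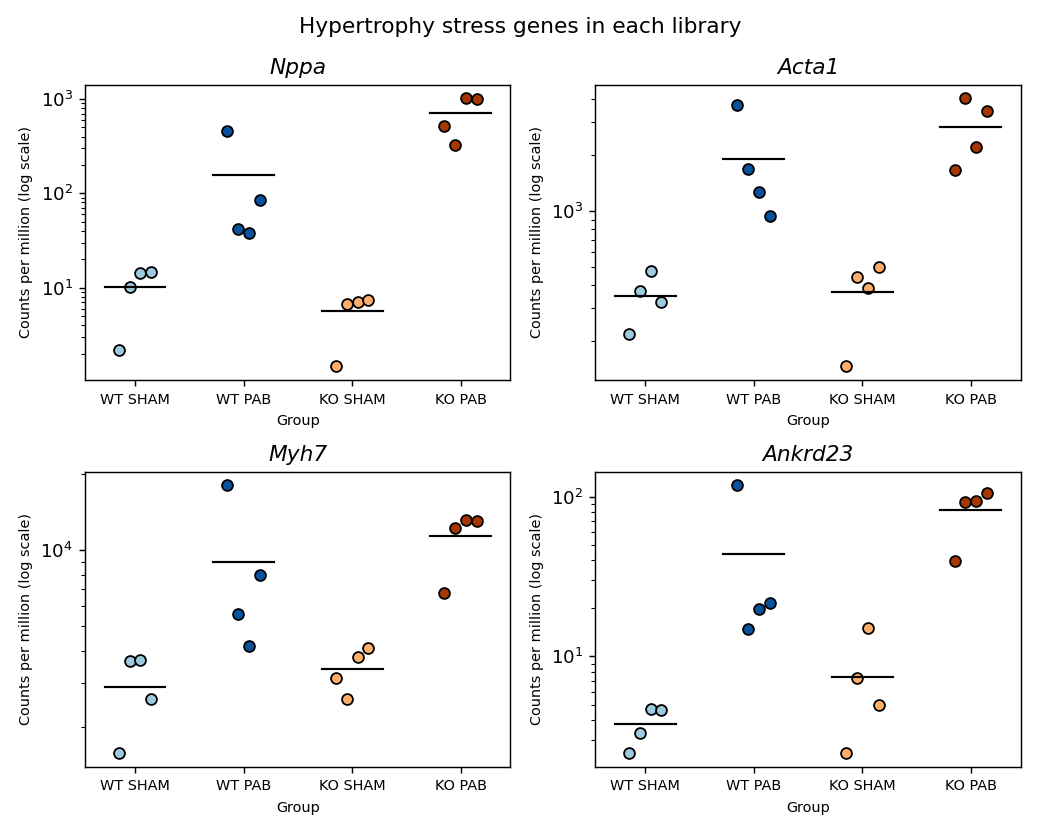
Level of Nppa, Acta1, Myh7 and Ankrd23 in each library, in CPM on a log axis, by group, with a line at the group mean. Nppa reached 462 CPM in WT PAB 1 and 38.0 to 85.0 CPM in the other 3 WT PAB libraries.

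Of the 24 tested genes of hypertrophy stress, 14 rose and none fell in the averaged comparison, with a median log2 fold change of 0.90. Beside those above, the stretch-responsive ankyrin protein gene Ankrd1 rose by 1.26 and Mybpc2, a skeletal form of myosin-binding protein C, by 1.58. The list passed the camera test with an adjusted p of 1.17e-20. With an estimated correlation its adjusted p was 0.0729, and fry, which does not compare it with other genes, gave 0.00206. Adjusted over the list alone, 15 genes rose. Sarcomere genes had a median of 0.20 and passed the preset test (adjusted p 0.000469), with 1 of 19 members, the actin-severing cofilin Cfl2 (0.46), past the gene test. Their adjusted p with an estimated correlation was 0.971, and the list did not pass without the 3 sham libraries (median 0.0437) or with the adipocyte and mesothelial score as a covariate (median 9.33e-05, test turned downward). Skeletal muscle markers also passed (median 0.66, adjusted p 0.0353, and 0.326 with an estimated correlation), with Mybpc2 as the only 1 of 5 members to rise.

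Matrix genes were mixed. In the basement membrane list the collagen IV chains Col4a1 (0.42) and Col4a2 (0.38) and the laminin chain Lama5 (0.80) rose, and Lama3 fell (−1.002), of 21 genes. The median was −0.03 and the list did not pass (adjusted p 0.562). In the TGF-beta list of 25 genes the ligand Tgfb2 rose by 2.16 (SE 0.40), while Tgfbi (−0.57) and the co-receptor Tgfbr3 (−0.48) fell, with a median of −0.10 against a mean of 0.05 (adjusted p 0.835). Fibrillar matrix genes had a median of −0.29 (adjusted p 0.156), and 1 of 41, the proteoglycan osteoglycin Ogn, fell (−0.51). The collagens Col1a1 and Col3a1 both differed by −0.24 and periostin (Postn) by −0.27, with adjusted p of 0.781, 0.756 and 0.813. Without the 3 sham libraries the medians turned to 0.52 for fibrillar matrix and 0.38 for TGF-beta signalling, and the difference in Postn to 1.34.

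Markers of cell types that were high in the 3 sham libraries had lower medians after banding. Of 11 mesothelial markers 5 fell, among them Msln (−4.37), Lrrn4 (−4.49), Muc16 (−4.55) and Gpm6a, with a median of −3.46 (adjusted p 0.000463, and 0.971 with an estimated correlation). Of 17 smooth muscle and pericyte markers 3 fell, Myh11 (−2.48), Tagln (−2.79) and Cnn1 (−3.64), with a median of −0.27 against a mean of −1.10 (adjusted p 0.0253, and 0.971 with an estimated correlation). Adipocyte markers had a median of −2.28 and did not pass (adjusted p 0.148). Without the 3 sham libraries the medians were −1.19 for mesothelial and −0.04 for smooth muscle markers, and neither list passed. The 3 were picked by their adipocyte and mesothelial scores, so the change in mesothelial markers was largely built in.

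Lymphocyte markers had a median of −0.39 (adjusted p 0.0353, and 0.971 with an estimated correlation), and the T cell genes Cd2 (−1.24) and Cd3g (−0.98) fell, of 15. In the Schwann and neuronal list, which did not pass (median −0.31, adjusted p 0.186), Cdh19 fell, as given above, and the adhesion molecule gene Ncam1 rose (1.97). Interferon and antigen presentation genes (median 0.11, adjusted p 0.0446), cell cycle genes (0.33, 0.0353) and ribosomal protein genes (−0.12, 0.0157) passed the preset test with no member past the gene test, and each had an adjusted p of 0.971 with an estimated correlation.

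Among genes of metabolism and excitability, single members passed in lists that did not. The ketone body enzyme Bdh1 rose by 0.81 (SE 0.11), 1 of 34 genes of the tricarboxylic acid cycle and branched-chain amino acid list, whose median was 0.00. Of 27 glycolysis genes the hexokinase Hk1 rose (0.46) and the muscle enolase Eno3 fell (−0.56), around a median of 0.07. The pacemaker channel gene Hcn2 rose by 0.90, 1 of 28 genes of calcium handling and excitability (median 0.04), and the natriuretic peptide clearance receptor Npr3 by 1.24, 1 of 19 vasoactive genes (median −0.17). Of 25 antioxidant genes Gpx1 (0.42) and Txnrd1 (0.28) rose and Gsta4 fell (−0.44), around a median of 0.05. The clock repressor Cry2 rose (0.64), 1 of 18 clock genes with a median of 0.17, as did the hypoxia-inducible prolyl hydroxylase Egln3 (0.53), 1 of 25 genes of angiogenesis and hypoxia with a median of −0.03. The type 2 BMP receptor Bmpr2 differed by 0.30 (adjusted p 0.0641) and apelin (Apln) by −0.27 (adjusted p 0.249), neither past the test.

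**Figure D4:**
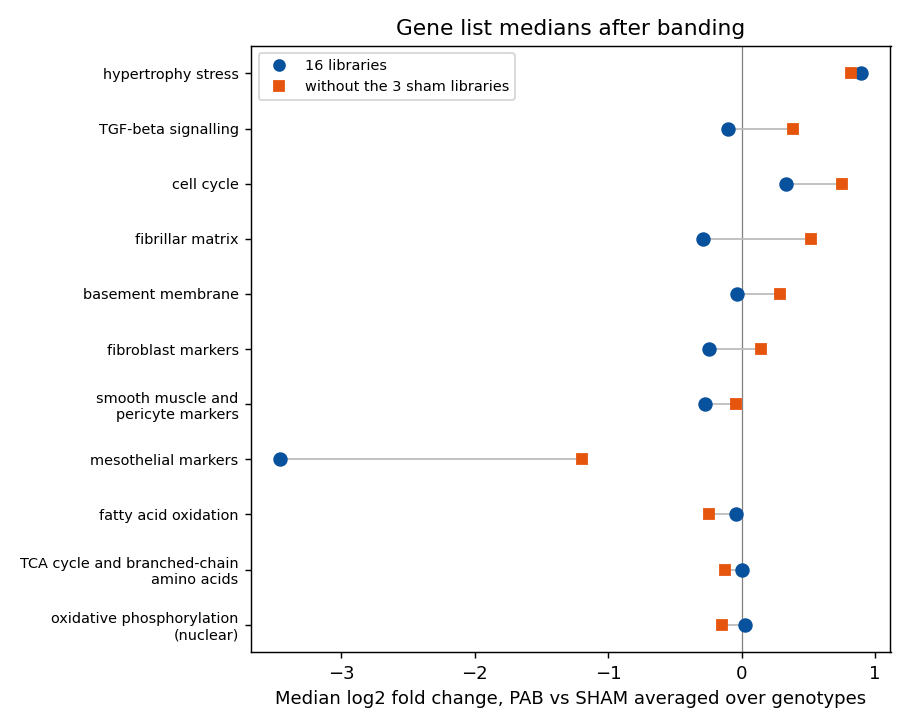
Median log2 fold change after banding, averaged over genotypes, for 11 gene lists, with all 16 libraries (circles) and without WT SHAM 2, WT SHAM 3 and KO SHAM 4 (squares). The hypertrophy stress median was 0.90 and 0.82, while fibrillar matrix moved from −0.29 to 0.52 and mesothelial markers from −3.46 to −1.19. The libraries left out were picked in part by their mesothelial score, so the last change was largely built in.

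Without the 3 sham libraries 951 genes passed in the averaged comparison, 520 higher and 431 lower, and 419 of them were among the 685. 14 lists passed the preset test without them, against 9 with all 16 libraries, of which 4 kept their direction and their call. The count also fell to 437 without WT SHAM 3, 361 without WT PAB 1, 456 without KO SHAM 2, 356 without KO PAB 2 and 363 without KO PAB 4, and DESeq2 gave 1337.

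In WT alone, the question is how the heart with ERalpha responds to load. A single gene passed the test, Dusp15, which rose by 2.36 (SE 0.30, adjusted p 0.0143), from 1.58 ± 0.376 to 8.10 ± 4.47 CPM (SD, n = 4). The stress genes had similar directions without passing: Nppa 3.93 (SE 0.87, adjusted p 0.197), Acta1 2.44 (SE 0.47, adjusted p 0.179), Ankrd23 3.52 (SE 0.71, adjusted p 0.179), Ankrd1 1.16 (SE 0.23, adjusted p 0.179), Myh7 1.63 (SE 0.41, adjusted p 0.230) and Nppb 1.70 (SE 0.72, adjusted p 0.3997). Postn differed by −1.43, Col3a1 by −0.73, Col1a1 by −0.60, Bmpr2 by 0.26, Apln by −0.11 and Myh6 by 0.01, none past the test. At an unadjusted p under 0.05 there were 1575 genes, against 672.9 expected by chance.

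16 lists passed the preset test in WT, 7 up and 9 down, and none with an estimated correlation or by exact tests of the scores per library (lowest adjusted p 0.762). The hypertrophy stress score reached the smallest unadjusted exact p possible (0.0286), with every WT PAB library above every WT SHAM library. Hypertrophy stress had a median of 0.83 (adjusted p 1.81e-14, and 0.213 with an estimated correlation), and adjusted over the list alone 12 of its 24 genes rose and 1 fell. Fibrillar matrix had a median of −0.73 (adjusted p 5.29e-05), fibroblast markers −0.60 (0.00126) and macrophage and monocyte markers −0.48 (0.00262), each with an adjusted p of 0.663 with an estimated correlation and no member past the gene test. Adipocyte markers had a median of −3.98 (adjusted p 0.0309) and mesothelial markers −3.39 (0.000568), with Adipoq at −7.11 and Lrrn4 at −3.91, neither past the gene test. Their adjusted p with an estimated correlation was also 0.663. Nuclear genes of oxidative phosphorylation had a median of 0.13 (adjusted p 5.29e-05) and ribosomal proteins −0.15 (6.22e-07), again 0.663 with an estimated correlation. Without the 3 sham libraries, of which WT SHAM holds 2, the median was 0.67 for hypertrophy stress and turned to 0.49 for fibrillar matrix, 0.22 for fibroblast markers, 0.23 for macrophage and monocyte markers and −0.12 for oxidative phosphorylation, and 3 of the 16 lists kept their direction and their call.

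Dusp15 missed the threshold in WT without WT SHAM 1, 2 or 4, where no gene passed. No gene passed either in limma-voom (1369 genes at an unadjusted p under 0.05), limma-voom with quality weights (1492), the 2-group fit (1078), the fit without the 3 sham libraries (1014) or that with the covariate (1385). DESeq2 called 108 genes, 87 higher and 21 lower.

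In KO the same comparison asks how the heart without ERalpha responds. 85 genes passed, 69 higher and 16 lower. Nppa rose by 6.99 (SE 1.01, adjusted p 0.0220), Acta1 by 2.95 (SE 0.48, adjusted p 0.0250), Ankrd23 by 3.49 (SE 0.70, adjusted p 0.0396) and Tgfb2, a ligand of the TGF-beta family, by 2.82 (SE 0.58, adjusted p 0.0458). Other large rises were in Cdhr1 (3.75), Tceal7 (3.53), Rbm44 (3.46), Sypl2 (3.13), Akip1 (3.02), the synaptic vesicle fusion gene Cplx1 (2.37), Vash2 (2.36) and Gba3 (2.30). Among the falls were Scn7a (−1.03), Slc22a3 (−1.03), Mum1l1 (−0.997), the adhesion molecule gene L1cam (−0.93), the transcription factor Foxp2 (−0.82), the ceramide synthase Cers4 (−0.82) and the regulatory subunit of PI3 kinase Pik3r1 (−0.69, SE 0.10, adjusted p 0.0202). Smaller falls were in the GATA cofactor Zfpm2 (−0.57), Abhd14b (−0.56), the ligand Wnt5a (−0.53), Laptm4b (−0.47) and Jmjd8 (−0.35).

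Of the 24 hypertrophy stress genes 6 rose in KO and none fell, with a median of 0.94 (adjusted p 1.34e-18, and 0.0773 with an estimated correlation). They include Ankrd1 (1.36) and Xirp2 (1.84), whose protein binds actin at the intercalated disc. Adjusted over the list alone, 15 rose and 1 fell. Bdh1 (0.85) and Npr3 (1.70) rose too, in the tricarboxylic acid cycle list (median −0.09, adjusted p 0.513) and the vasoactive list (median −0.09, adjusted p 0.661). Tgfb2 was the only 1 of 25 TGF-beta genes past the test (median 0.09, adjusted p 0.563). Myh7 differed by 1.73 (adjusted p 0.0602), Nppb by 2.55 (0.122), Myh6 by −0.35 (0.532), Postn by 0.88 (0.659), Col3a1 by 0.25 (0.876), Col1a1 by 0.12 (0.958), Bmpr2 by 0.34 (0.209) and Apln by −0.43 (0.295).

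8 lists passed the preset test in KO, 3 up and 5 down, and none by exact tests of the scores per library (lowest adjusted p 0.571). Beside hypertrophy stress these were cell cycle (median 0.73, adjusted p 0.00208) and skeletal muscle markers (0.56, 0.0362) upward, and mesothelial markers (−3.53, 0.00255), smooth muscle and pericyte markers (−0.33, 0.0292), lymphocyte markers (−0.23, 0.04996), fatty acid oxidation (−0.14, 0.04996) and immediate early genes (−0.42, 0.04996) downward. No member of these 7 passed the gene test. With an estimated correlation the adjusted p was 0.269 for the skeletal muscle markers and 0.957 for the other 6. Failure of the adjusted exact tests decides little, since they can pass only if many lists reach the smallest possible p together. Hypertrophy stress and skeletal muscle scores both reached it (unadjusted exact p 0.0286), with every KO PAB library above every KO SHAM library. KO SHAM 4 is 1 of the 3 libraries high in mesothelial and smooth muscle markers, and without the 3 libraries 4 of the 8 lists kept their direction and their call.

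The count in KO depended on single libraries. It was 0 without KO SHAM 1, 0 without KO SHAM 2, 1 without KO SHAM 3, 147 without KO PAB 1, 0 without KO PAB 2, 33 without KO PAB 3 and 0 without KO PAB 4. It was 344 without the 3 sham libraries, with 78 of the 85 among them, and 509 with DESeq2, with all 85 among them. With the replicate number as a block it was 0 in edgeR (1958 at an unadjusted p under 0.05), though the numbers did not pair the samples.

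The effects of banding in WT and KO were then set side by side. Across the 13458 tested genes the log2 fold changes correlated with r 0.545 (Spearman 0.498), and 68.4% had the same sign. This is a correlation across genes, which are not independent replicates, and without KO SHAM 4 it was 0.148. All 685 genes of the averaged comparison differed in the same direction in WT and in KO, which is largely built in, since they were selected for the mean of both effects in these libraries. For 490 of the 685 the estimate was larger in KO, and the median size was 0.44 in WT and 0.56 in KO.

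**Figure D5:**
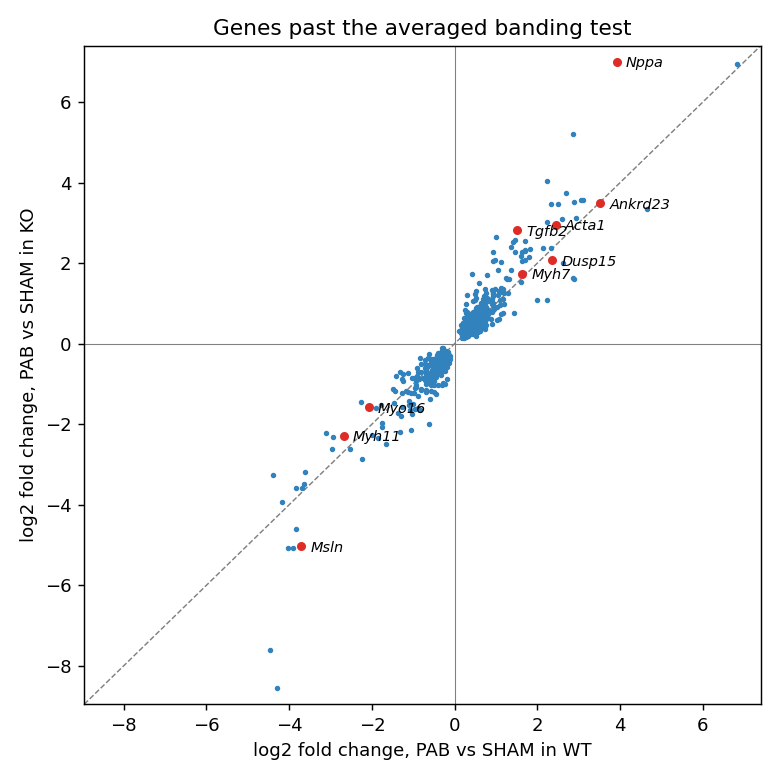
Log2 fold change after banding in WT (x axis) and in KO (y axis) for the 685 genes past the test in the averaged comparison, each point 1 gene, with 9 genes labelled and a dashed line of equal change. The genes were selected for the mean of both effects, and Nppa is at 3.93 in WT and 6.99 in KO.

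The difference itself, the interaction of genotype and banding, was past the edgeR test for 0 genes. 237 genes had an unadjusted p under 0.05, below the 672.9 that chance gives, and DESeq2 and limma-voom also called 0, with 246 and 242 at that level. A count below chance is not evidence that no gene differs, since the 3 sham libraries add to the spread within their groups. The interaction was 3.07 for Nppa (SE 1.14, unadjusted p 0.0175, adjusted p 0.999), 0.51 for Acta1, 0.10 for Myh7, 0.86 for Nppb, −0.36 for Myh6, 0.72 for Col1a1, 0.99 for Col3a1, 2.31 for Postn, 0.08 for Bmpr2 and −0.32 for Apln, none past the test. The smallest p belonged to the ribosomal protein gene Rps18l1 (0.76), the potassium channel gene Kcnj8 (−0.64), the matrix gene Omd, Rasgef1c (−1.62) and Rnf157 (1.57), with an adjusted p of 0.999. Omd was listed at 0 in all libraries of some groups, so no fold is given. In simulated data 50.7% of 2-fold interactions were recovered, and smaller ones were mostly missed. Those data drew each gene on its own, without the difference shared by the 3 sham libraries. Recovery in the real libraries may therefore be lower, and a count of 0 leaves room for differences of 2-fold and more.

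18 lists passed the preset test for the interaction, 11 with the larger value in KO and 7 in WT, and none with an estimated correlation. Fibrillar matrix had a median of 0.72 (adjusted p 1.65e-07), macrophage and monocyte markers 0.75 (5.20e-07), cell cycle genes 0.66 (0.000808) and hypertrophy stress 0.25 (0.0103), each with an adjusted p of 0.646 with an estimated correlation. Nuclear genes of oxidative phosphorylation had a median of −0.21 (1.01e-07, and 0.680 with an estimated correlation), fatty acid oxidation −0.22 (2.23e-05, and 0.646) and immediate early genes −0.43 (5.20e-07, and 0.646). No gene of any list was past the gene test. WT SHAM holds 2 and KO SHAM 1 of the 3 sham libraries that stand apart, and without them 5 lists passed, 4 of the 18 among them with their direction.

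Between genotypes in sham hearts, which asks what loss of ERalpha does without load, Esr1 was the only gene past the test. It was lower in KO by a log2 fold change of −2.97 (SE 0.24, adjusted p 3.74e-05), in 4 of 4 libraries. The stress genes did not differ beyond the spread: Nppa −0.87, Nppb −0.36, Acta1 0.07, Myh7 0.24 and Myh6 −0.06. The collagens Col1a1 (−0.49) and Col3a1 (−0.57), Postn (−1.49), Bmpr2 (−0.03) and Apln (0.04) also did not pass, all with an adjusted p of 0.996. 273 genes had an unadjusted p under 0.05, below the 672.9 expected by chance. With the 3 sham libraries adding to the spread within the sham groups, this is not evidence that no gene differs.

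Among 17 tested oestrogen receptor and responsive genes, Esr1 was the only 1 to fall in sham hearts, and Lcn2 (−0.32), C3 (−0.73) and Rarg (−0.25), a retinoic acid receptor, did not pass. The list's median was −0.01 and its preset test gave an adjusted p of 0.0137, a call that rests on a list holding Esr1 itself. Fibrillar matrix (median −0.48, adjusted p 2.42e-06), adipocyte markers (−2.08, 0.0137) and ribosomal proteins (−0.15, 1.35e-17) were also among the 18 lists past the preset test, 6 up and 12 down. The adjusted p with an estimated correlation was 0.790 for all 18, and the lowest by exact tests of the scores per library was 0.908. Without the 3 sham libraries 3 lists passed and 2 of the 18 kept their direction and their call, the median of fibrillar matrix was 0.04, and that of the ribosomal proteins was −0.11.

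Between genotypes under load, Esr1 was again the only gene past the test, lower in KO by −3.34 (SE 0.25, adjusted p 1.30e-05) in 4 of 4 libraries. Nppa was higher in KO by 2.20 (SE 0.80, unadjusted p 0.0159), Acta1 by 0.58, Nppb by 0.50, Myh7 by 0.34, Postn by 0.82, Col3a1 by 0.42, Col1a1 by 0.23 and Bmpr2 by 0.05, while Myh6 differed by −0.41 and Apln by −0.28, all with an adjusted p of 0.999. 608 genes had an unadjusted p under 0.05. DESeq2 called 5 genes, among them the kinase Slk (0.44) and the matricellular gene Cyr61 (−1.49), which were named after their values were seen.

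12 lists passed the preset test between genotypes under load, and none with an estimated correlation. The count was 7 without KO PAB 3. By exact tests of the scores per library no list passed after adjustment (lowest adjusted p 0.381). Endothelial, angiogenesis and hypoxia, and smooth muscle and pericyte scores each reached the smallest unadjusted exact p possible (0.0286). In each of them every KO PAB library lay below every WT PAB library. The unadjusted exact p was 0.143 for mast cell and granulocyte and for immediate early genes. It was 0.171 for macrophage and monocyte markers and 0.200 for hypertrophy stress. Immediate early genes had a median of −0.56 (adjusted p 0.000224, and 0.955 with an estimated correlation), with Fos at −1.83, Jun at −1.06, Dusp1 at −0.78 and Klf6 at −0.62, none past the gene test. Fos averaged 153 ± 113 CPM in WT PAB and 42.8 ± 9.88 CPM in KO PAB (SD, n = 4). Macrophage and monocyte markers had a median of 0.46 (0.000224, and 0.955), with Tyrobp at 0.56, Gpnmb at 0.67, Adgre1 at 0.74 and Trem2 at 0.92. Mast cell and granulocyte markers had a median of 0.93 (0.000245, and 0.211), with the mast cell proteases Cpa3 at 1.33, Tpsb2 at 0.69 and Cma1 at 1.09 and the neutrophil protein S100a9 at 1.67. None of these markers passed the gene test.

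Hypertrophy stress genes had a median of 0.28 between genotypes under load (adjusted p 0.000224, and 0.561 with an estimated correlation), cytokines and complement 0.34 (0.00261, and 0.955) and cell cycle genes 0.27 (0.0162, and 0.955). Lower in KO were oxidative phosphorylation (−0.11, 0.000224, and 0.955), fatty acid oxidation (−0.13, 0.00454, and 0.955), angiogenesis and hypoxia (−0.10, 0.00792, and 0.174), endothelial markers (−0.12, 0.00261, and 0.356) and smooth muscle and pericyte markers (−0.36, 0.0136, and 0.955). Oestrogen receptor and responsive genes, a list that holds Esr1 itself, had a median of −0.14 (0.000550, and 0.174), with the chemokine Cxcl12 at −0.54 and Igf1 at 1.18, neither past the gene test.

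Averaged over surgeries, KO and WT differed past the test in Esr1 alone (−3.16, SE 0.17, adjusted p 1.56e-07), lower in 8 of 8 KO libraries. The adenylate cyclase gene Adcy2 came next at −0.92 (SE 0.14, adjusted p 0.0649), with 0.714 to 1.21 CPM in the KO libraries and 1.36 to 1.91 CPM in the WT libraries, and was past the threshold in DESeq2 (adjusted p 0.000394), limma-voom (0.0368) and limma-voom with quality weights (0.0343). It was named after its values were seen. Nppa differed by 0.66, Acta1 by 0.33, Myh7 by 0.29, Nppb by 0.07, Myh6 by −0.24, Col1a1 by −0.13, Col3a1 by −0.07, Postn by −0.34, Bmpr2 by 0.01 and Apln by −0.12, none past the test. The genotype effect in sham hearts and that under load correlated across genes with r −0.031 (Spearman 0.052), and from −0.153 (without WT PAB 2) to 0.156 (without KO PAB 3) with 1 library left out.

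9 lists passed the preset test in this average, 4 up and 5 down, and none with an estimated correlation. They include ribosomal proteins (median −0.10, adjusted p 1.05e-09, and 0.904 with an estimated correlation), hypertrophy stress (0.19, 0.00758, and 0.904) and the oestrogen list, which holds Esr1 itself (−0.17, 0.000158, and 0.154), in which Cxcl12 (−0.26), Rarg (−0.29) and Stc2 (−0.25) did not pass. Without the 3 sham libraries 3 of the 9 kept their direction and their call.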

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

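The tests of a lower cardiomyocyte share, of other tissue as the reason for the low WT count, of unequal banded WT hearts and of a larger response without ERalpha were chosen after their results had been seen, and the other tests here before. The search covered list scores, library measures such as the total count, and levels of genes named for averaged banding or given throughout. Over these 69 measures 276 groups of 4 libraries were searched for a library far from its 3 group mates. Dixon's test set its gap against the group's range at the 95% level. 31 such values were found in 9 libraries. Chance gives about 1 in 20 groups, 13.8 here, if values within a group are normally distributed, which was not checked. Gene levels were searched as CPM and not on a log scale, where a single high library stands out less. The excess over 13.8 therefore decides little. The measures overlap in their genes, so the 31 are not independent.

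KO SHAM 4 held 9 of the 31 values. Its scores, with those of the other KO SHAM libraries in brackets, were −1.20 for sarcomere (0.115 to 0.315), −1.01 for the tricarboxylic acid cycle (0.622 to 0.828), −1.37 for oxidative phosphorylation (0.378 to 0.615), 1.32 for fibrillar matrix (−0.837 to −0.505), 1.301 for fibroblast markers (−0.575 to −0.332), 0.993 for matrix crosslinking (−0.545 to −0.335) and 1.02 for vasoactive genes (−0.353 to −0.176). Its Postn was 23.6 CPM (3.91 to 6.11) and its Slc22a3 12.3 CPM (20.0 to 20.9). WT SHAM 2 held 5, an immediate early score of −2.32 (0.479 to 0.527), an oestrogen score of 0.788 (−0.0584 to 0.0729), Myo16 at 1.29 CPM (3.55 to 3.86), Abca8 at 6.44 (3.04 to 3.33) and Gca at 7.14 (5.84 to 5.92).

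WT SHAM 2, WT SHAM 3 and KO SHAM 4 share high adipocyte, mesothelial and smooth muscle markers, and also high fibroblast (median log2 difference 1.15), macrophage (1.19) and lymphatic markers (1.40). Cartilage and valve markers were higher too (2.85 over 6 genes). A lower share of cardiomyocytes alone would raise all other cell types alike. Adipocyte markers exceeded endothelial markers by 4.44 in median log2 difference, but the 3 were picked for their adipocyte and mesothelial scores. That excess was therefore largely built in, and several adipocyte genes were near 0 CPM in the other sham libraries. Among lists not used to pick the 3, macrophage markers differed by 1.19 (quartiles 1.06 to 1.35) and endothelial markers by −0.06 (quartiles −0.38 to 0.32). This unlike change argues against a lower cardiomyocyte share alone. Mesothelium in the piece of tissue is a candidate explanation: a second set of mesothelial genes differed by a median of 1.89 (quartiles 1.42 to 2.14) with Pkhd1l1 at 60.3 against 15.9 CPM, though this does not single it out from the other cell types that were high. For adipose tissue the second set gave 0.810 (quartiles 0.265 to 1.77, Fasn 70.9 against 8.00 CPM). This lies below the bound of 1 set for it and above that of 0.3 set against it, so this test leaves it open. Some genes of that set were high in the other 5 as well (Gpd1 167 CPM), so its median decides little. Among the 15 adipocyte markers, 10 were higher in all 3 than in all of the other 5, and 1 was lower. Adipoq was 11.1 to 45.6 CPM in the 3 and at most 0.0461 in the other 5, and Plin1 2.80 to 11.2 against 0. Transcripts of these adipocyte genes were thus present in the 3. All 21 tested genes of the second sets were also detected in the other 5 sham libraries, and since all 3 are sham libraries, a difference between hearts or in how a piece was taken was not tested.

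WT PAB 1 held 8 of the 31 values. Beside the other 3 WT PAB libraries it had Nppa at 462 CPM (38.0 to 85.0), Ankrd23 at 118 (14.8 to 21.7), Cdhr1 at 4.38 (0.424 to 0.872), Sypl2 at 18.1 (2.24 to 4.26), Rbm44 at 3.50 (0.388 to 0.733), Akip1 at 16.7 (2.49 to 4.68), Lsamp at 3.27 (7.63 to 8.40) and Slc22a3 at 9.61 (13.5 to 14.0). Gene levels were searched only for genes named for averaged banding and for the fixed set. That its 8 genes are among those named for banding was therefore built in. All 8 lie further from the sham level than in the other 3. The naming rule asked for no overlap with sham libraries, which limits values toward the sham level, so this decides little. These gaps were not tested on a log scale.

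Banding passed the test for 1 gene in WT and 85 in KO, while the interaction passed for 0 in edgeR (237 at an unadjusted p under 0.05), DESeq2 and limma-voom. With the adipocyte and mesothelial score as a covariate the edgeR counts were 0 in WT (1385 at an unadjusted p under 0.05) and 634 in KO. The WT count met the bound set against other tissue in the sham libraries as the whole cause. That bound was set after the counts had been seen. The score also covers only some of the marker lists that were high in these libraries, so other tissue stays open. Unequal response among the banded WT hearts may contribute: the SD of the hypertrophy stress score was 0.524 in WT PAB and 0.163 in KO PAB, with an exact p of 0.257, so it stays open. A larger response without ERalpha stays open too, since the banding score over the 685 genes was 0.950 ± 0.184 in KO PAB and 0.508 ± 0.506 in WT PAB (SD, n = 4; exact p 0.171, where 0.0286 is the smallest possible). Those genes were chosen for their banding effect in these libraries, and the WT values were 1.26 in WT PAB 1 and 0.176 to 0.325 in the other 3.

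KO PAB 1 had Myh7 at 6791 CPM (12248 to 13199 in the other 3), Myo16 at 3.50 (0.533 to 0.916) and Gca at 4.44 (2.93 to 3.19). KO SHAM 1 had an angiogenesis score of −0.292 (0.0906 to 0.109) and Nppa at 1.46 CPM (6.75 to 7.41). Single values were Cdhr1 in WT SHAM 4 (0.0822 CPM, others 0.277 to 0.293), Esr1 in KO SHAM 3 (0.425, others 0.576 to 0.589), the interferon score in KO PAB 2 (0.673, others −0.0712 to −0.0231) and the lymphatic score in KO PAB 3 (1.15, others −0.572 to −0.407).

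Banding effects of 18 lists differed between genotypes by the preset camera test of the interaction, and none with an estimated correlation (adjusted p 0.306 to 0.680). Their medians, KO minus WT, were 1.51 for mast cell and granulocyte, 0.81 for lymphatic, 0.75 for macrophage and monocyte and 0.63 for fibroblast markers, 0.75 for cytokines and complement, 0.72 for fibrillar matrix, 0.66 for cell cycle, 0.48 for matrix crosslinking, 0.25 for hypertrophy stress, 0.13 for ribosomal proteins and 0.12 for TGF-beta signalling. They were −0.43 for immediate early genes, −0.26 for endothelial markers, −0.22 for fatty acid oxidation, −0.21 for oxidative phosphorylation, −0.21 for the tricarboxylic acid cycle, −0.12 for sarcomere and −0.12 for angiogenesis and hypoxia. Without WT SHAM 2 the count was 10, and without the 3 sham libraries 5, where the medians of sarcomere and fibroblast markers turned to 0.0208 and −0.0534.

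Genes near Esr1 can carry alleles of the strain in which the mutation was made, a candidate explanation for genotype differences that recur in both surgeries. The test planned for genes past the threshold within 20 Mb of Esr1 had 0 genes other than Esr1 to work on and decided nothing. Of the 100 nearest tested genes, 50 on each side in the order of the GRCr8 assembly, 10% had an unadjusted p under 0.05 for KO against WT averaged over surgeries, against 4.89% of 13357 other genes (Fisher exact p 0.0316). Adcy2 is the 12th tested gene on one side, and its low p had been seen before this test. Neighbouring genes are not independent, and an effect of ERalpha itself on these genes stays open.

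Counts of genes were also set against other splits of the same libraries. For banding in KO 1 of 35 splits, the real one, gave 85 genes and the highest other 0. For banding averaged over genotypes 1 of 100 gave 685 and the highest other 1. These shares (0.0286 and 0.01) are the smallest such splits allow, so chance is unlikely there but not excluded. A count of 1 was also reached by other splits, so the count alone cannot tell an effect from chance. This holds in WT banding (4 of 35, highest other 1), in KO against WT in sham hearts (5 of 35, highest other 1346) and under load (3 of 35, highest other 8), and averaged (9 of 100, highest other 1926). For the interaction the comparison decides nothing, since every split reaches a count of 0 (100 of 100, highest other 832). The split with 1346 genes set WT SHAM 2 to 4 and KO SHAM 4 against the rest, which points to the structure of the 3 sham libraries. A count of 1 says nothing of how small the p of Esr1 was. Esr1 was the 1 gene in each comparison of genotypes. Its level was 0.248 to 0.589 CPM in the KO libraries and 2.69 to 5.53 CPM in the WT libraries, which argues against chance for Esr1.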

How the results depend on the processing

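The fit without the 3 sham libraries, the covariate and the quality weights were chosen after the data were seen, and the other alternatives before. Of the values for named genes under an alternative, 3812 kept direction and side of the threshold, 511 lost the call and 21 gained it. In 1 the direction reversed where the main or the alternative fit held a call, and in 100 it changed where neither did. For lists the counts were 1222, 229, 20, 27 and 25. Gene counts stayed within 1.5 times in 119 cases, rose in 14 and fell in 21. The cause was not tested for the changes below, except that fits without libraries hold fewer of them. Esr2 and Pgr had too few counts to be tested, and 13748 gene entries had none. Whether depth or absent expression is the reason was not tested.

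Genes past the test after banding in WT were 108 with DESeq2 and 0 with limma-voom, 0 with quality weights, 0 in the 2-group fit, 0 without the 3 sham libraries and 0 with the covariate (1014 to 1492 genes at an unadjusted p under 0.05 in these 5). In KO they were 509 with DESeq2, 1375 with quality weights, 0 with a replicate block (1958 at an unadjusted p under 0.05), 155 in the 2-group fit, 344 without the 3 sham libraries and 634 with the covariate. Averaged over genotypes they were 1337 with DESeq2, 1283 with quality weights and 280 with a minimum fold of 1.5. DESeq2 kept all 85 genes of the KO comparison and all 685 of the averaged one. KO against WT under load gave 5 with DESeq2 and 3 with quality weights, and averaged over surgeries 12 with DESeq2, 2 with limma-voom and 4 with quality weights.

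Leaving out 1 library in turn gave 0 to 1 genes in WT (0 without WT SHAM 1, 2 or 4), 0 to 147 in KO (0 without KO SHAM 1, KO SHAM 2, KO PAB 2 or KO PAB 4, 1 without KO SHAM 3, 33 without KO PAB 3, 147 without KO PAB 1) and 356 to 964 in the average (437 without WT SHAM 3, 361 without WT PAB 1, 456 without KO SHAM 2, 356 without KO PAB 2, 363 without KO PAB 4). The correlation of banding effects between genotypes ranged from 0.148 (without KO SHAM 4) to 0.647.

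Lists past the test were 0 in all 7 comparisons with an estimated correlation. In KO banding 5 passed with the stricter filter, 4 with a block and 18 with the covariate, and in banding averaged over genotypes 14 without the 3 sham libraries and 19 with the covariate. In KO against WT sham hearts 3 passed without the 3 and 6 with the covariate, and in the interaction 5 without the 3. Leaving out 1 library gave 7 to 23 in WT banding (7 without WT SHAM 2), 6 to 24 in KO against WT sham hearts (6 without WT SHAM 2, 10 without WT SHAM 3, 8 without KO SHAM 1, 6 without KO SHAM 3) and 7 to 16 under load (7 without KO PAB 3). It gave 10 to 23 in the interaction (10 without WT SHAM 2), 5 to 16 in averaged banding (5 without WT PAB 3, 16 without WT SHAM 4) and 5 to 16 in averaged genotype (5 without KO SHAM 1, 14 without WT SHAM 1, 16 without WT SHAM 4, 15 without KO SHAM 4).

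Lists that kept direction and call without the 3 sham libraries, and with the covariate, were 3 and 3 of 16 in WT banding, 4 and 5 of 8 in KO banding, 2 and 2 of 18 in KO against WT sham hearts, 12 and 12 of 12 under load, 4 and 14 of 18 in the interaction, 4 and 4 of 9 in averaged banding and 3 and 4 of 9 in averaged genotype. The comparison under load uses no sham library. Leaving out the 3 could change it only through the filter, the scaling and the shared estimate of spread, so its 12 of 12 says little. Medians of lists whose test turned in direction, without the 3 and with the covariate, were in WT banding 0.49 and 0.53 for fibrillar matrix, −0.12 and −0.16 for oxidative phosphorylation, 0.0756 and 1.85 for adipocyte, 0.22 and 0.29 for fibroblast and 0.23 and 0.40 for macrophage markers. Mesothelial markers had −0.18 with the covariate, where the test turned upward and the median stayed negative. The covariate is the sum of the adipocyte and mesothelial scores, and the 3 libraries were picked by them. Changes of the adipocyte and mesothelial lists under these fits were therefore largely built in. In KO against WT sham hearts they were 0.0398 and −0.0266 for fibrillar matrix and 0.0769 and −0.0846 for adipocyte markers, where with the covariate the tests turned upward and both medians shrank but stayed negative. Plin1 and other adipocyte genes were at or near 0 in the other 5 sham libraries, so the adipocyte medians without the 3 rest on few counts.

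In averaged banding they were 0.52 and 0.66 for fibrillar matrix, 0.38 and 0.38 for TGF-beta signalling and −0.13 and −0.16 for the tricarboxylic acid cycle, that of sarcomere shrank to 9.33e-05 with the covariate, where the test but not the median turned downward, and Postn had a log2 fold change of 1.34 without the 3. In the interaction sarcomere had 0.0208 and 0.0261, and −0.23 to 0.0181 with 1 library left out (0.0181 without WT SHAM 2). Fibroblast markers had −0.0534 without the 3, and 0.00277 (without WT SHAM 2, where the test but not the median turned) to 0.90 with 1 library left out.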

Other observations

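The fit without WT SHAM 2, WT SHAM 3 and KO SHAM 4 was chosen after the data were seen, as were the genes named from it and the windows other than 50 genes around Esr1. Banding averaged over genotypes then changed genes of matrix, growth factor signalling and cell division of which most named here did not pass with all 16 libraries (Tgfb2, Tgfbi and Tgfbr3 did). Of 41 fibrillar matrix genes 8 rose, among them tenascin C (Tnc 1.85), Col12a1 (0.97), Col8a1 (1.60), Postn (1.34), the thrombospondin Thbs4 (3.31) and Ltbp2 (2.57), with a list median of 0.52. Of 26 TGF-beta genes 8 rose, among them Ctgf (1.92), Tgfb2 (2.79), Nox4 (1.26) and Gdf15 (3.15), and 2 fell, Tgfbi (−0.44) and Tgfbr3 (−0.36). Of 30 tested genes of matrix crosslinking and turnover 2 rose, the lysyl oxidase genes Loxl1 (1.44) and Loxl2 (0.70), with a median of 0.23, while Lox (0.24), Loxl3 (0.23) and Loxl4 (0.84) did not pass.

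Of 23 cell cycle genes 6 rose without the 3 sham libraries, among them Top2a (1.25), Mki67 (0.76), Cdk1 (1.62) and Tpx2 (1.32), with a median of 0.75. Of 42 fatty acid oxidation genes 3 fell, Hadhb (−0.55), Decr1 (−0.57) and Hadh (−0.52), and of 52 nuclear genes of oxidative phosphorylation 6 fell, among them Cox8b (−0.34), with medians of −0.24 and −0.15. Of 24 hypertrophy stress genes 12 rose and 1, Cyr61 (−0.75), fell. These lists passed the preset camera test. With an estimated correlation the adjusted p was 0.722 for each list of this and the preceding paragraph. Only 5 sham libraries remain in this fit.

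Other tools called genes between genotypes that edgeR did not. Under load DESeq2 gave Slk (0.44), Cyr61 (−1.49), Rpn2 (−0.26) and Cbr1 beside Esr1, and limma-voom with quality weights gave Slk (0.50) and the hepcidin gene Hamp (2.53). Averaged over surgeries the genes DESeq2 gave include Adcy2 (−0.93), Spon2 (−1.43), Hsd11b1 (0.56), which encodes an enzyme that activates glucocorticoids, Igsf1 (0.50), Isoc2b (−0.58), Pkdcc (−0.35), Rab40b (0.45), Rpn2 (−0.18), Tsen34 (0.50) and Tsen34l1 (−0.60) beside Esr1. In edgeR the adjusted p of all of these but Adcy2 was 0.598 to 0.999. For Cbr1 no fold is given.

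Around Esr1 the share of tested genes with an unadjusted p under 0.05 was 4 of 20 with 10 genes on each side (Fisher exact p 0.0151), 5 of 50 with 25 (0.0985), 18 of 200 with 100 (0.0125) and 28 of 312 with up to 200 (0.00208). The widest window reached an end of the chromosome and is not even on both sides. Its share was 8.97%, against 9% with 100 genes on each side, 10% with 50 or 25 and 20% with 10. Its lower p thus came with more genes and not with a larger share. The windows are nested and not independent. The 10 genes among the nearest 100 were Adcy2 (−0.92), Slc9a3 (0.85), Acat2 (0.52), Rgs17 (0.50), Myct1 (−0.38), Tppp (−0.37), Mthfd1l (0.35), Eya4 (0.30), Syne1 (−0.26) and Pdcd6 (0.19), and none passed the adjusted test.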
